A study of Mus musculus with 18 samples.

How the data were processed

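Colon tissue of male C57BL/6J mice was profiled by RNA sequencing in 18 libraries, 6 for each of 3 groups named Control, Model and AKK in the labels. Per the labels' protocols, polyadenylated RNA that passed a check of its integrity was made into strand-marked (dUTP) libraries and sequenced as read pairs on a NovaSeq instrument. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1 and StringTie 2.1.6 were used with the mm10 genome build. The same notes name DESeq2 and edgeR with neither version nor role. The annotation release and the strand setting of the counting are not given in the sources used here, so values of genes that overlap on opposite strands are uncertain. The same holds for gene families with near-identical members, among them the immunoglobulin constant genes and the Reg3 genes.

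The deposited table held 36451 gene identifiers with 2 values per library. Per the file headers, the first was the FPKM, fragments per kilobase of transcript scaled to the library's mapped fragments. Per the file headers, the second was an estimated count, which the authors deposited as whole numbers, so no rounding was needed. In 12794 genes with 100 or more counts in all libraries, 99.9% of the ratios of count to FPKM lay within 1% of a constant for the gene and library, so both columns carried the same measurement. Values of 4, 8 and 12 counts were 2.36, 1.74 and 1.36 times as frequent as their neighbours, so 1 sequenced fragment appeared to contribute about 4 counts. Dividing by 4 was tried as an alternative. No pair of libraries held identical values, and the lowest chi-square per degree of freedom of any pair was 13.9, so all 18 were kept as separate samples. Chromosome, start and end are those of the deposited table on mm10.

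Total counts ranged from 53873744 to 82589848 per library. The labels give no sequencing batch. Totals above 70000000 were found in 3 AKK libraries, 1 Model library and 0 Control libraries, and fits without these libraries were added. Each library is named by its title. The labels do not say that each library came from a separate animal, so the p-values measure only the spread between these libraries, which may in part be technical.

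Groups, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The plan named limma on log2(FPKM + 1) as the main test, for a table of FPKM alone. Since the deposited table also held counts, edgeR's quasi-likelihood test on the counts became the main test, and the limma fit was kept as an alternative. Genes with an FPKM of at least 1 in at least 6 libraries were tested, which left 14007. Counts were scaled by TMM, and 1 model with a term for each group was fitted over all 18 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 with their standard errors. Means ± SD are of FPKM. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used, and figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

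Of 37 gene lists, 34 had at least 5 tested members. They cover ferroptosis and iron, sterol synthesis, the cell cycle, respiration, and markers of epithelial, immune and stromal cells and of other tissues. Each was tested with fry in limma, adjusted over the 34 lists. This test asks whether the members move, on balance, one way, and does not compare them with other genes. camera with a preset correlation of 0.01 or an estimated correlation was the alternative. KEGG terms in the deposited table were tested for enrichment among called genes by a one-sided Fisher exact test, with 303 terms of 10 to 500 tested genes in both directions, which made 606 tests per comparison. The background was the 5196 tested genes with any term.

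The genes named are, per comparison, the 6 largest rises and 6 largest falls in log2(FPKM + 1) among called genes whose groups did not overlap, without predicted models and without immunoglobulin or T cell receptor segments. Where fewer were called, only those were taken. For each list described by members, the 2 called members with the largest change were added, or those with the smallest p where none was called. Gpx4, Slc7a11, Acsl4, Tfrc, Fth1, Hmox1, Ptgs2 and Nfe2l2 were named whatever their result. Lists given as counts only have no named members. Some genes the rule names are not reported here. Krt5, Fabp6 and the other tissue markers in the last part were chosen after their values were seen.

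The tests were tried on simulated counts with the real means, library sizes and dispersions and 200 changed genes. For Model against Control, edgeR recovered 23.9% of 1.5-fold, 68.7% of 2-fold and 92.4% of 4-fold changes. The shares were 32.8%, 68.7% and 92.4% for AKK against Model, and 31.3%, 59.7% and 87.9% for AKK against Control. The sterol synthesis list, raised 1.3-fold, was called, and 0 of the other simulated lists were. Genes were simulated independently, whereas the estimated correlation within a real list reached 0.918 (B cell genes, Model against Control). The simulation therefore does not gauge how often real lists are called falsely.

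The alternatives were other filters, scalings, pseudocounts, tools and covariates, fits of each pair of groups alone, and fits without each library in turn. Fits without mitochondrial genes, without Model_1337 and Model_1341, without the deepest libraries, with Hoxb13 or epithelial markers as a covariate, with DESeq2 and with counts divided by 4 were chosen after the data had been seen. The study's design text also mentions the ferroptosis agonist Erastin, and no group given it was analysed here.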

Results

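The series asked whether Akkermansia muciniphila (AKK), a mucin-degrading gut bacterium, affects colitis through ferroptosis, a form of cell death driven by iron-dependent lipid peroxidation. Colon RNA was sequenced in 6 libraries of each of 3 groups. Control mice were 6 weeks old and kept without a stated treatment. The labels give no age for the Model and AKK mice, so a difference in age cannot be told apart from the treatments. Model mice drank 3% dextran sulfate sodium (DSS), which injures the colon epithelium, for 1 week and were given saline by gavage. AKK mice were given 0.1 mL of the bacterium by gavage once a week for 6 weeks. The labels state DSS for the Model group only, so whether the AKK mice also received it is not given in the sources used here. The numbers of the libraries do not overlap between the groups, so each comparison also holds any difference between cohorts that the numbers follow. Total counts were 53873744 to 65705141 per Control library, 58841661 to 79147073 per Model library and 60665457 to 82589848 per AKK library.

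Model against Control compares mice given DSS and saline gavage with the Control mice. B cell and plasma cell genes rose. The plasma cell protein Mzb1 (ENSMUSG00000024353, chromosome 18, 35647267 to 35649367) had an FPKM of 52.4 ± 43.2 (SD, n = 6) in Model and 5.46 ± 1.81 (SD, n = 6) in Control. Its log2 change of 3.19 ± 0.46 (SE) had an adjusted p of 0.00092 (edgeR, Benjamini-Hochberg). The immunoglobulin heavy chain genes Ighg3 and Ighg2b rose by 7.26 ± 1.04 and 6.45 ± 0.81 on the log2 scale (SE, edgeR adjusted p 0.000919 and 0.000524). The B cell receptor gene Cd79a rose by 3.43 ± 0.56 (SE, edgeR adjusted p 0.00192), and Fcrla, a B cell protein, rose by 3.73 ± 0.68 (SE, edgeR adjusted p 0.0031). Immunoglobulin genes took 0.383 ± 0.107% (SD, n = 6) of the counts in Control and 2.35 ± 1.68% (SD, n = 6) in Model. Model_1341, with 17% of its counts from mitochondrial genes, was at 0.319%, and the other 5 Model libraries at 1.18 to 4.56%. Of 18 plasma cell genes, edgeR called 17 higher, and 17 when adjusted over the list alone (fry adjusted p = 0.00354, adjusted p = 0.192 with an estimated correlation). Of 10 B cell genes, 9 were called higher, and 10 when adjusted over the list alone (fry adjusted p = 0.0242, adjusted p = 0.406 with an estimated correlation). Without Model_1337 the B cell list had an adjusted p of 0.0585. Without Model_1340 the log2 change was 2.75 for Cd79a and 3.09 for Fcrla, and without Control_2668 it was 8.43 for Ighg3.

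Matrix and vessel genes also rose. Of 33 extracellular matrix genes 26 were called higher, and 27 higher and 1 lower when adjusted over the list alone (fry adjusted p = 0.00123, adjusted p = 0.192 with an estimated correlation). Lox, which crosslinks collagen, and the matrix protein Fn1 rose by 2.17 ± 0.37 and 1.75 ± 0.32 on the log2 scale (SE, edgeR adjusted p 0.00242 and 0.00303). The microfibril protein Mfap4 was at 40.4 ± 13.9 FPKM in Model and 9.4 ± 2.55 FPKM in Control (SD, n = 6), a log2 change of 2.06 ± 0.21 (SE, edgeR adjusted p 0.000102). Of 19 endothelial genes 15 were called higher, and 18 when adjusted over the list alone (fry adjusted p = 0.00596, adjusted p = 0.365 with an estimated correlation). The tight junction gene Cldn5 rose by 1.55 ± 0.36 (SE, edgeR adjusted p 0.00948), and by 0.94 without Model_1337. Selp, an adhesion molecule of activated endothelium, rose by 2.89 ± 0.82 (SE, edgeR adjusted p 0.022), and without Model_1337 its log2 change was 1.06 (adjusted p 0.131). Of 21 smooth muscle genes 8 were called higher, with Tagln at 1.20 ± 0.28 and Csrp1 at 1.11 ± 0.27 (log2 ± SE, edgeR adjusted p 0.00881 and 0.0104). That list was not called (fry adjusted p = 0.0618), and 14 members passed when adjusted over the list alone. It was called without Control_2285 (0.0338) and without Model_1339 (0.0216). Its genes called higher numbered 13 without Control_2285, 2 without Model_1337, Control_2286, Control_2287 or Control_2288, 3 without Model_1316 or Model_1341 and 4 without Control_2289. With the smooth muscle genes as a covariate, 213 genes were called in place of 2797.

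The protease inhibitor Slpi was at 69.2 ± 65.6 FPKM in Model and 3.11 ± 2.14 FPKM in Control (SD, n = 6), a log2 change of 4.41 ± 0.73 (SE, edgeR adjusted p 0.00199), and of 3.82 without Model_1340. Ly6d, a surface protein of the Ly6 family, rose by 4.12 ± 0.85 (SE, edgeR adjusted p 0.00545), and by 2.18 without Model_1337. Of 16 genes of fetal-like epithelial repair 9 were called higher, and 10 higher and 1 lower when adjusted over the list alone (fry adjusted p = 0.0192, adjusted p = 0.421 with an estimated correlation). The growth factor-binding matrix protein gene Ccn2 was at 23.5 ± 16 FPKM in Model and 6.02 ± 2.93 FPKM in Control (SD, n = 6, edgeR adjusted p 0.00707). The annexin gene Anxa1 rose by 2.67 ± 0.74 on the log2 scale (SE, edgeR adjusted p 0.0207). Anxa1 stood at 1049 FPKM in Model_1337, where the squamous keratin Krt5 stood at 1059 FPKM against at most 0.328 FPKM in the other Model libraries. Without Model_1337 the log2 change of Anxa1 was 0.64 (adjusted p 0.0701). Without Control_2668 the repair list had a fry adjusted p of 0.0544, and without Model_1337 5 of its genes were called higher. Of 20 macrophage genes 6 were called higher, and 6 higher and 1 lower when adjusted over the list alone, while the list was not called (fry adjusted p = 0.185, and 0.0105 without Model_1341). Without Model_1337 1 and without Model_1340 3 macrophage genes were called higher. The mannose receptor Mrc1 rose by 1.48 ± 0.36 and the arginase Arg1 by 5.78 ± 1.42 (log2 ± SE, edgeR adjusted p 0.0112 and 0.0114). Arg1 stood at 372 FPKM in Model_1337 and between 0.987 and 2.75 FPKM in the other 5, and without Model_1337 its log2 change was 0.81 (adjusted p 0.0774). Of 8 neutrophil genes 3 were called higher, and 6 when adjusted over the list alone, with the list not called (fry adjusted p = 0.175). The 3 became 0 without Model_1337 or Control_2288, 6 without Model_1341 and 1 without Model_1316, Model_1340, Control_2668, Control_2285, Control_2286 or Control_2287.

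Sterol synthesis and cell cycle genes fell. Of 22 genes of cholesterol synthesis and its control, 17 were called lower, and 18 when adjusted over the list alone, with a median log2 change of -0.51 (fry adjusted p = 3.24e-07, adjusted p = 0.00731 with an estimated correlation). Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), an early synthase of the pathway, was at 46.8 ± 7.01 FPKM in Model and 83 ± 6.85 FPKM in Control (SD, n = 6). Its log2 change was -0.87 ± 0.09 (SE, edgeR adjusted p 0.000102). Sqle, squalene epoxidase, fell by 0.71 ± 0.10 (SE, edgeR adjusted p 0.000919). Of 30 cell cycle genes 28 were called lower, and 30 when adjusted over the list alone (fry adjusted p = 0.00354, adjusted p = 0.277 with an estimated correlation). Cyclin A2 (Ccna2) and survivin (Birc5) fell by 1.06 ± 0.22 and 1.03 ± 0.26 on the log2 scale (SE, edgeR adjusted p 0.00542 and 0.0137). Of 36 genes of oxidative phosphorylation 12 were called lower, and 13 when adjusted over the list alone, with the list not called (fry adjusted p = 0.0618). It was called without Model_1338, Model_1341 and Model_1339 (0.03, 0.0121 and 0.0461). Its genes called lower numbered 19 without Model_1341, 6 without Control_2286 and 7 without Model_1316 or Model_1340. Cycs and Ndufs1 of the respiratory chain fell by 0.81 ± 0.22 and 0.73 ± 0.13 (SE, edgeR adjusted p 0.018 and 0.00254).

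The largest falls were in genes of the antimicrobial Reg3 lectins. Reg3b (ENSMUSG00000071356, chromosome 6, 78370657 to 78373466) was at 6935 ± 5313 FPKM in Control and 75.2 ± 88.2 FPKM in Model (SD, n = 6), a log2 change of -6.58 ± 1.42 (SE, edgeR adjusted p 0.00677). Reg3g and Reg3a fell by 6.10 ± 1.24 and 4.90 ± 1.31 on the log2 scale (SE, edgeR adjusted p 0.00516 and 0.0167), and Reg3a fell by 5.85 without Model_1339. Control libraries ranged from 551 to 14418 FPKM in Reg3b. Of 19 antimicrobial genes 2 were called higher and 4 lower, and 3 higher and 4 lower when adjusted over the list alone, with the list not called (fry adjusted p = 0.151). The 2 higher became 1 without Model_1316, Model_1337, Model_1340, Control_2668, Control_2285, Control_2286, Control_2287 or Control_2288. Art2a, an ADP-ribosyltransferase, and Ms4a18 fell by 2.05 ± 0.51 and 2.86 ± 0.77 (SE, edgeR adjusted p 0.0124 and 0.0172). Slc51b, part of the bile acid exporter, fell by 1.61 ± 0.51 (SE, edgeR adjusted p 0.0342). Its adjusted p was 0.0763, 0.0637, 0.0528, 0.0649 and 0.0676 without Control_2286, Control_2288 and Control_2289 and Model_1316 and Model_1340. The distal hindgut list was called higher (fry adjusted p = 0.032, adjusted p = 0.583 with an estimated correlation), though 0 of its 7 genes were called, and 0 when adjusted over the list alone. Its Hoxb13, a transcription factor gene of the distal hindgut, was at 20.8 ± 39.5 FPKM in Model and 0.826 ± 1.99 FPKM in Control (SD, n = 6, log2 change 4.59 ± 2.07, edgeR adjusted p 0.124, and 0.0204 without Control_2285). Hoxb13 stood at 100.3 FPKM in Model_1340 and between 0 and 18.3 FPKM in the other 5 Model libraries, and without Model_1340 its log2 change was 2.42. Hoxa11 had a log2 change of 0.74 ± 0.45 (SE, edgeR adjusted p 0.243). That list had adjusted p of 0.079, 0.0556 and 0.0659 without Model_1337, Model_1341 and Model_1340, and of 0.0544, 0.095, 0.0754 and 0.0773 without Control_2668, Control_2286, Control_2287 and Control_2288.

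Ferroptosis genes as lists were not called between Model and Control. Of 36 genes of the KEGG ferroptosis pathway 2 were called higher and 2 lower, and 1 and 1 when adjusted over the list alone (fry adjusted p = 0.429). Of 24 suppressors 2 were called lower, and 1 when adjusted over the list alone (fry adjusted p = 0.086), and of 25 drivers 1 was called higher and 2 lower, and 1 and 2 when adjusted over the list alone (fry adjusted p = 0.875). The test for changes in either direction gave adjusted p of 0.0112, 0.00175 and 0.0314 in fry for these lists. It called 23 of the 34 lists in this comparison, so a pass is not particular to ferroptosis genes. Without Model_1338, without Model_1341 and with quantile normalization the suppressor list was called lower (fry adjusted p 0.03, 0.0473 and 0.0353), and over 28 alternatives its adjusted p reached 0.472. Pathway genes called higher numbered 7 without Model_1341, 5 without Model_1339 and 1 without Model_1337, Control_2285, Control_2286 or Control_2288, and those called lower 1 without Control_2285, Control_2286, Control_2288, Control_2289, Model_1316 or Model_1340. Drivers called higher numbered 4 without Model_1341, 2 without Model_1338, Model_1339 or Control_2289 and 0 without Control_2668, Control_2285, Control_2286 or Control_2288. Drivers called lower numbered 1 without Control_2285 or Control_2286 and 0 without Control_2288, Control_2289, Model_1316 or Model_1340, and suppressors called lower 1 without Control_2287 or Model_1340. Fdft1, squalene synthase, which also belongs to sterol synthesis, fell by 0.62 ± 0.08 (SE, edgeR adjusted p 0.000524). The lipoxygenase gene Alox15 rose by 1.81 ± 0.55 (SE, edgeR adjusted p 0.0305), the mitochondrial channel gene Vdac2 fell by 0.51 ± 0.16 (SE, edgeR adjusted p 0.0348), and the mitochondrial iron-sulfur protein gene Cisd2 fell by 0.26 ± 0.08 (SE, edgeR adjusted p 0.0307). Alox15 was not called without Model_1337 (log2 change 0.88, adjusted p 0.116) or without Control_2668, Control_2285, Control_2286 and Control_2288 (0.0504, 0.0592, 0.0501 and 0.0578). Vdac2 was not called without Control_2285, Control_2286, Control_2288 and Control_2289 (0.0556, 0.0784, 0.0741 and 0.0653) or Model_1316 and Model_1340 (0.0672 and 0.0566). Cisd2 was not called without Model_1337 and Model_1340 (0.055 and 0.0518) or Control_2287 (0.0529).

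The 7 tested genes named for the question in advance were not called between Model and Control. Gpx4, the lipid peroxide reductase that restrains ferroptosis, was at 66.7 ± 14 FPKM in Model and 53.4 ± 6.39 FPKM in Control (SD, n = 6, log2 change 0.29 ± 0.14, edgeR adjusted p 0.145). The log2 changes ± SE were 0.73 ± 0.25 for Acsl4 (adjusted p 0.0531), -0.54 ± 0.22 for Tfrc (0.0892), 0.06 ± 0.20 for Fth1 (0.861), 0.79 ± 0.32 for Hmox1 (0.0868), 0.46 ± 0.38 for Ptgs2 (0.404) and -0.25 ± 0.21 for Nfe2l2 (0.422), all by edgeR. Gpx4 was called without Model_1316 (0.0488), Acsl4 without Model_1338, Model_1341 and Model_1339 and Control_2289 (0.0487, 0.00951, 0.0418 and 0.0479), Tfrc without Control_2668 (0.0212) and Hmox1 without Model_1341 (0.0236). Fth1 had the opposite sign with TPM or quantile scaling and without Model_1338, Control_2285 or Control_2289, and Nfe2l2 with library weights. The cystine transporter gene Slc7a11 lay below the filter, at 0.288 ± 0.244 FPKM in Control, 2.03 ± 3.01 in Model and 0.807 ± 0.208 in AKK (SD, n = 6), and its Model mean rested on 8.16 FPKM in Model_1337. With no filter its log2 change was 2.61 ± 0.68 (SE, edgeR adjusted p 0.0341).

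**Figure D1:**
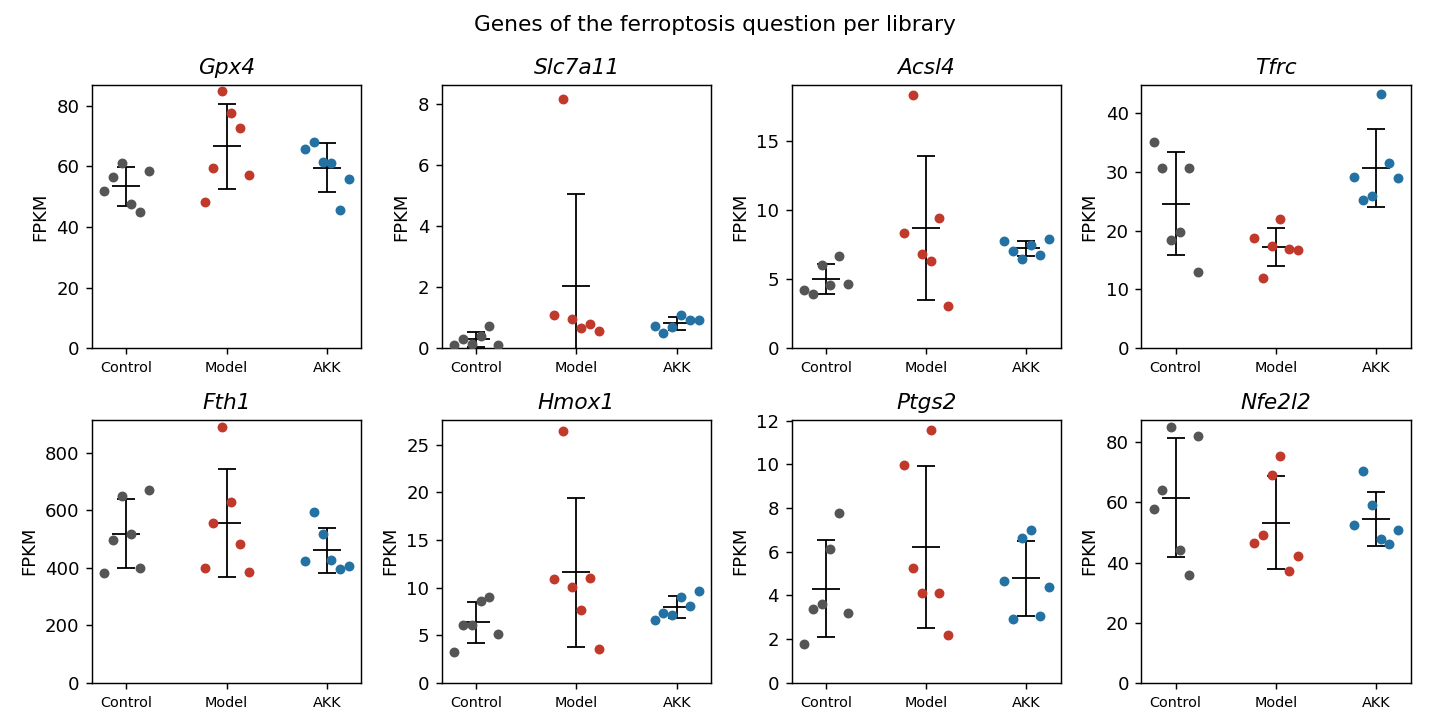
FPKM (vertical axes, from 0) of the 8 genes named in advance for the ferroptosis question in the Control, Model and AKK groups (horizontal axes). Points are libraries, and bars are the mean ± SD (n = 6). The highest Slc7a11 point is Model_1337 at 8.16 FPKM, and Tfrc is higher in all 6 AKK libraries (25.2 to 43.3 FPKM) than in the 6 Model libraries (12 to 22 FPKM).

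Of 14007 genes, edgeR called 2797 between Model and Control, 1733 higher and 1064 lower, and 764 of them changed at least 2-fold. The groups did not overlap in 407 genes, 2.91% against 0.216% by chance. Of 606 tests of KEGG terms 46 were enriched (Fisher exact test, adjusted), led by cell adhesion molecules (41 of 100 genes higher) and cytokine receptor interaction (52 of 148 higher), with the proteasome among those lower (22 of 43). The Ferroptosis term had 2 of 37 genes higher and 2 lower and was not enriched. Higher genes made up 34.9% of the calls with TPM scaling and 44.8% with quantile normalization. Of 34 lists, 8 were called and 26 were not (fry adjusted p 0.0618 to 0.875), and without Model_1341 14 lists were called. Fitting both groups alone gave 903 calls, DESeq2 3567 and the exact rank sum test 0 (3413 at an unadjusted p under 0.05), and without Control_2286 edgeR gave 1721. The exact rank sum p cannot fall under 0.00216 with 6 against 6 libraries, so a count of 0 after adjustment does not show an absence of change.

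AKK against Model asks how colon RNA of mice given the bacterium differed from that of the Model mice. Sterol synthesis genes were higher in AKK. Of 22 genes 2 were called higher over all genes and 16 when adjusted over the list alone, with a median log2 change of 0.41 (fry adjusted p = 4.2e-06, adjusted p = 6.54e-05 with an estimated correlation). The 2 became 1 without any 1 library other than Model_1316. Hmgcs1 was at 80.5 ± 8.06 FPKM in AKK and 46.8 ± 7.01 FPKM in Model (SD, n = 6), a log2 change of 0.73 ± 0.09 (SE, edgeR adjusted p 0.00179). Aacs (ENSMUSG00000029482, chromosome 5, 125475814 to 125517410), which makes acetoacetyl-CoA from acetoacetate, was at 28.9 ± 2.32 FPKM in AKK and 17.9 ± 2.41 FPKM in Model (SD, n = 6), a log2 change of 0.63 ± 0.08 (SE, edgeR adjusted p 0.00442). Hmgcs1 and Aacs, of which Aacs is not on the list, were 2 of the 3 genes edgeR called. Both were higher in 6 of 6 AKK libraries than in any Model library.

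**Figure D2:**
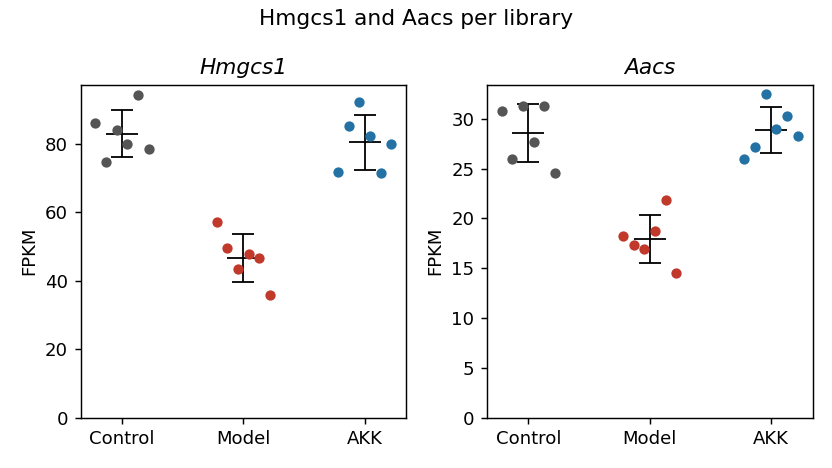
FPKM (vertical axes, from 0) of Hmgcs1 and Aacs in the Control, Model and AKK groups (horizontal axes). Points are libraries, and bars are the mean ± SD (n = 6). Hmgcs1 lies between 71.3 and 92.3 FPKM in AKK and between 35.9 and 57.2 FPKM in Model.

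The 4 libraries above 70000000 counts comprised 3 AKK and 1 Model library. Without them 0 genes were called (639 at an unadjusted p under 0.05), with Hmgcs1 at 0.78 ± 0.12 and Aacs at 0.63 ± 0.12 (log2 ± SE, edgeR adjusted p 0.178 and 0.856), and the sterol list stayed called (fry adjusted p = 0.0015). Adjusted p over all alternatives ran from 3.66e-15 to 0.365 for Hmgcs1 and from 3.33e-09 to 0.856 for Aacs. The number of calls was 0 when both groups were fitted alone (864 at an unadjusted p under 0.05), 0 by the exact rank sum test (865), 12 by DESeq2 and 14 with library weights. An unadjusted p under 0.05 was found in 932 genes by edgeR, against 700.4 by chance, and the groups did not overlap in 112 genes, 0.8% against 0.216% by chance. TPM scaling moved the median log2 change of all genes by 0.14. Of 34 lists, 33 were not called (fry adjusted p 0.262 to 0.979).

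**Figure D3:**
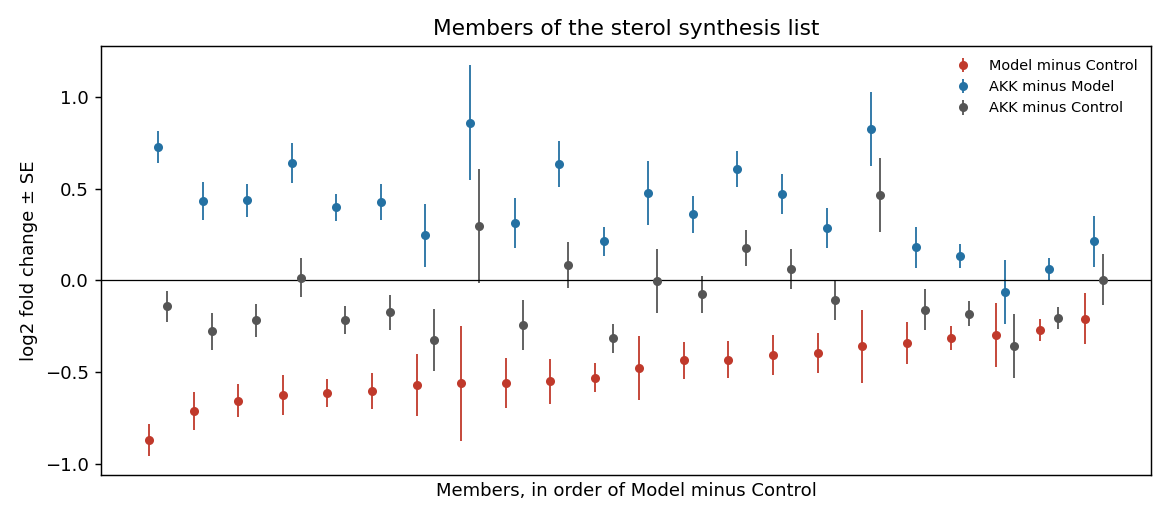
Log2 fold change ± SE (vertical axis) of the 22 members of the sterol synthesis list (horizontal axis, in order of the first comparison) for Model minus Control, AKK minus Model and AKK minus Control. The median member lies at -0.51, 0.41 and -0.15 in these comparisons.

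Ferroptosis genes did not pass the test between AKK and Model. Of 36 pathway genes, 24 suppressors and 25 drivers, edgeR called 0, and adjusted over the list alone 0, 1 and 0 were called. The fry adjusted p of these lists was 0.758, 0.877 and 0.979, and in 28 alternative settings each stayed above the threshold, the lowest being 0.43, 0.218 and 0.405. Suppressors with the smallest p were Fdft1 (log2 change 0.40 ± 0.08, edgeR adjusted p 0.153) and Dhodh (0.23 ± 0.09, 0.732). Tfrc had the smallest p among both the pathway genes and the drivers. It was followed by Map1lc3a (-0.24 ± 0.11, 0.732) in the pathway and by Sat1 (-0.27 ± 0.12, 0.732) among the drivers. The transferrin receptor gene Tfrc, which imports iron, was at 30.7 ± 6.6 FPKM in AKK and 17.3 ± 3.27 FPKM in Model (SD, n = 6). Its log2 change of 0.76 ± 0.22 (SE) was higher in 6 of 6 AKK libraries but not called (edgeR adjusted p 0.718). The log2 changes ± SE of the others were -0.23 ± 0.14 for Gpx4 (adjusted p 0.757), -0.29 ± 0.25 for Acsl4 (0.802), -0.33 ± 0.20 for Fth1 (0.759), -0.57 ± 0.32 for Hmox1 (0.75), -0.41 ± 0.38 for Ptgs2 (0.81) and -0.02 ± 0.21 for Nfe2l2 (0.985), all by edgeR. Acsl4 had the opposite sign with TPM scaling, with library weights and without Model_1337, and Nfe2l2 in 12 alternatives. With no filter Slc7a11 had a log2 change of -1.24 ± 0.65 (SE, edgeR adjusted p 0.501). Of the KEGG tests 3 were enriched, butanoate metabolism, terpenoid backbone synthesis and branched-chain amino acid degradation, each with 2 of the 3 called genes. The Ferroptosis term held 0 of them.

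AKK against Control compares mice given the bacterium with the Control mice. Plasma cell and matrix genes were higher in AKK. Of 18 plasma cell genes 14 were called higher, and 17 when adjusted over the list alone (fry adjusted p = 0.00435, adjusted p = 0.166 with an estimated correlation). Without Control_2288 and without AKK_1309 9 were called. Ighg3 and Ighg2c rose by 6.57 ± 1.01 and 5.28 ± 0.94 on the log2 scale (SE, edgeR adjusted p 0.00268 and 0.00589), and Mzb1 by 2.63 ± 0.45 (SE, edgeR adjusted p 0.00421). Without Control_2668 the log2 change of Ighg3 was 7.74. Immunoglobulin genes took 1.69 ± 0.592% (SD, n = 6) of the AKK counts. Of 33 matrix genes 21 were called higher, and 27 higher and 1 lower when adjusted over the list alone (fry adjusted p = 0.000459, adjusted p = 0.0573 with an estimated correlation). Lox and Col12a1 rose by 2.35 ± 0.37 and 1.78 ± 0.29 (log2 ± SE, edgeR adjusted p 0.00295 and 0.0034). Mfap4 was at 45.8 ± 8.12 FPKM in AKK (SD, n = 6) and rose by 2.19 ± 0.21 on the log2 scale (SE, edgeR adjusted p 8.6e-05). Grem1 and Sfrp1, antagonists of BMP and Wnt signals made by stromal cells, rose by 2.64 ± 0.44 and 2.21 ± 0.33 (SE, edgeR adjusted p 0.00357 and 0.00215). Slpi and Lgi2 rose by 3.33 ± 0.69 and 2.52 ± 0.42 (SE, edgeR adjusted p 0.0143 and 0.00372).

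B cell, endothelial and cell cycle lists were called in AKK against Control as well, with weaker support. Of 10 B cell genes 5 were called higher, and 8 when adjusted over the list alone (fry adjusted p = 0.0365, adjusted p = 0.417 with an estimated correlation). Without Control_2668, Control_2285, Control_2286, Control_2288 and Control_2289 that list had adjusted p of 0.0536, 0.0735, 0.0705, 0.0684 and 0.0625, and without AKK_1302, AKK_1303, AKK_1306 and AKK_1309 of 0.0542, 0.0558, 0.0573 and 0.0616. Its genes called higher numbered 2 without Control_2285, Control_2286, Control_2288, Control_2289, AKK_1302, AKK_1306 or AKK_1309. Of 19 endothelial genes 8 were called higher, and 16 when adjusted over the list alone (fry adjusted p = 0.0214, adjusted p = 0.417 with an estimated correlation). Of 30 cell cycle genes 13 were called lower, and 27 when adjusted over the list alone (fry adjusted p = 0.0239, adjusted p = 0.417 with an estimated correlation). Without Control_2289, AKK_1302 and AKK_1309 the endothelial list had adjusted p of 0.0576, 0.0524 and 0.0532, and the cell cycle list of 0.0625, 0.0524 and 0.0603. Endothelial genes called higher numbered 2 without Control_2286, AKK_1302 or AKK_1309, 3 without Control_2288 or AKK_1306, 4 without Control_2285, Control_2289 or AKK_1310 and 5 without AKK_1305. Cell cycle genes called lower numbered 24 without Control_2668, 2 without Control_2286, Control_2288, AKK_1302 or AKK_1309, 3 without Control_2289 or AKK_1310, 5 without AKK_1306 and 6 without AKK_1305. The sterol list was not called (fry adjusted p = 0.132, 1 of 22 called lower, and 2 when adjusted over the list alone), and was called lower without Control_2668 (0.0363) and without Control_2288 (0.0467). Its genes called lower numbered 4 without Control_2668, 2 without Control_2285 and 0 without Control_2288, Control_2289 or any AKK library but AKK_1303.

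Reg3b was at 213 ± 202 FPKM in AKK (SD, n = 6), a log2 change of -5.12 ± 1.32 from Control (SE, edgeR adjusted p 0.0326). Of 19 antimicrobial genes 1 was called higher and 3 lower, and 1 higher and 4 lower when adjusted over the list alone (fry adjusted p = 0.614). The 3 lower became 1 without Control_2286, Control_2289 or AKK_1305 and 0 without Control_2288, AKK_1302, AKK_1306, AKK_1309 or AKK_1310. The lipid raft protein gene Mal, the resistin-like gene Retnla and the steroid dehydrogenase gene Akr1c18 fell by 3.52 ± 0.89, 3.34 ± 0.80 and 2.60 ± 0.68 (SE, edgeR adjusted p 0.03, 0.025 and 0.0334). Counts at the mitochondrial transfer RNA genes mt-Th and mt-Tl2 fell by 2.18 ± 0.46 and 2.15 ± 0.46 (SE, edgeR adjusted p 0.0147 and 0.0148). The libraries were made from polyadenylated RNA, so these counts may not measure transfer RNA. Control_2668 stood at 33.6 and 26.9 FPKM in these genes, against 6.32 to 12 and 5.1 to 9.33 in the other Control libraries. Reg3b was not called without Control_2286, Control_2288 and Control_2289 (0.0665, 0.0694 and 0.0502) or AKK_1302, AKK_1305, AKK_1306, AKK_1309 and AKK_1310 (0.0691, 0.0563, 0.0718, 0.0706 and 0.0697). Mal was not called without Control_2286 (log2 change -2.82, adjusted p 0.0759) and Control_2288 (0.0574) or AKK_1302, AKK_1305, AKK_1306, AKK_1309 and AKK_1310 (0.065, 0.0522, 0.0668, 0.0722 and 0.0607). Retnla was not called without Control_2286 (0.0558) or AKK_1302 and AKK_1309 (0.0584 and 0.0621). Akr1c18 was not called without Control_2286 and Control_2288 (0.0734 and 0.0721) or AKK_1302, AKK_1305, AKK_1306, AKK_1309 and AKK_1310 (0.0724, 0.0661, 0.076, 0.0721 and 0.0723).

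**Figure D4:**
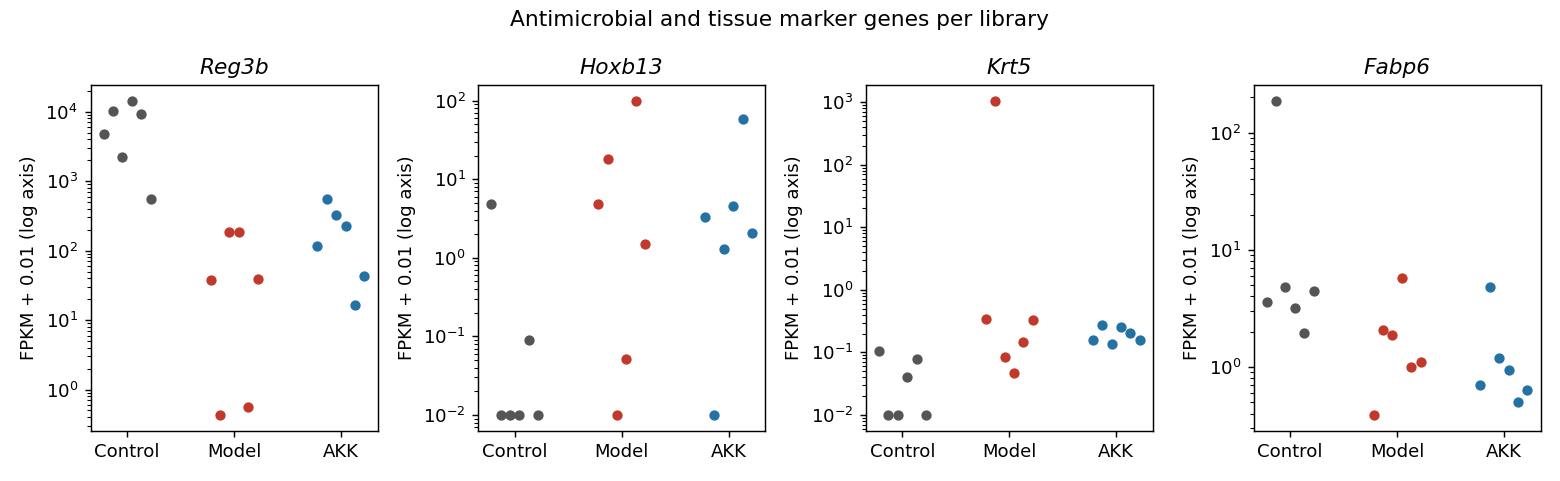
FPKM plus 0.01 (vertical axes, log scale) of Reg3b, Hoxb13, Krt5 and Fabp6 in the Control, Model and AKK groups (horizontal axes). Points are libraries. Krt5 reaches 1059 FPKM in 1 Model library, and Fabp6 reaches 187 FPKM in 1 Control library.

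Among ferroptosis genes, the lipid ligase gene Acsl5 fell by 0.48 ± 0.13 and the NADPH oxidase gene Nox1 rose by 1.72 ± 0.45 in AKK against Control (log2 ± SE, edgeR adjusted p 0.0345 and 0.0334). The pathway list had 1 gene lower and 0 when adjusted over the list alone, and the driver list 1 gene higher and 1 (fry adjusted p = 0.832 and 0.88). These were Acsl5 and Nox1. Of 24 suppressors 0 were called, and 0 when adjusted over the list alone (fry adjusted p = 0.159). Acsl5 was not called without Control_2286, Control_2288 and Control_2289 (0.0733, 0.0777 and 0.0681) or any AKK library (0.0667, 0.0537, 0.0613, 0.0668, 0.0735 and 0.0709 in order of their numbers). Nox1 was not called without Control_2286, Control_2287 and Control_2288 (0.0607, 0.059 and 0.0832) or AKK_1302, AKK_1306, AKK_1309 and AKK_1310 (0.0619, 0.0706, 0.0771 and 0.0665). The log2 changes ± SE were 0.06 ± 0.14 for Gpx4 (adjusted p 0.821), 0.43 ± 0.25 for Acsl4 (0.296), 0.21 ± 0.22 for Tfrc (0.565), -0.27 ± 0.20 for Fth1 (0.421), 0.22 ± 0.32 for Hmox1 (0.693), 0.05 ± 0.38 for Ptgs2 (0.953, with the opposite sign without Control_2668, Control_2285, Control_2286 or Control_2287 or AKK_1305 or AKK_1306) and -0.27 ± 0.21 for Nfe2l2 (0.442), all by edgeR. With no filter Slc7a11 had a log2 change of 1.37 ± 0.66 (SE, edgeR adjusted p 0.31).

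Between AKK and Control edgeR called 859 genes, 517 higher and 342 lower, and 256 changed at least 2-fold. The groups did not overlap in 1207 genes, 8.62% against 0.216% by chance. Of the KEGG tests 15 were enriched (Fisher exact test, adjusted), among them extracellular matrix receptor interaction (15 of 58 genes higher) and the proteasome (16 of 43 lower). Higher genes made up 48.9% of the calls with quantile normalization, 85.9% with TPM scaling and 50.2% by DESeq2. Of 34 lists, 5 were called and 29 were not (fry adjusted p 0.132 to 0.999), and without Control_2289, AKK_1302 or AKK_1309 2 lists were called. Without Control_2668, Control_2286, Control_2288 and Control_2289 the count was 1563, 282, 307 and 567, and without AKK_1302, AKK_1305, AKK_1306, AKK_1309 and AKK_1310 it was 351, 511, 338, 316 and 355. It was 2697 when both groups were fitted alone and 56 without the 4 libraries above 70000000 counts, of which Control had 0. Model against Control gave 903 calls when fitted alone, and 407 genes without overlap. The main fit pools the spread of each gene over groups whose mean distances between libraries differ (0.695 in Model, 0.392 in AKK, 0.478 in Control). The main counts of 2797 and 859 therefore do not rank these comparisons.

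Of the 3 genes called between AKK and Model, all 3 had been called lower in Model than in Control. Both comparisons share the Model libraries. In 20 simulations without effects the overlap was 0. Such data give few calls, so this 0 was all but fixed and decides nothing. Independent lists of the same lengths would share 0.228, and splitting the Model libraries into sets of 3 gave 0 to 18 with a median of 1. Across genes, which are not independent replicates, the log2 changes correlated at -0.55, against -0.50 in the simulations, with a covariance of -0.117 against -0.0422. With separate sets of 3 Model libraries in each comparison the median correlation was -0.18 (-0.35 to 0.49) and the median covariance -0.0463. The calls of Model and AKK against Control shared 739 genes in the same direction, 454 higher and 285 lower. The simulated overlap was 0, which decides nothing for the same reason. Independent lists would share 64 higher and 26 lower, and splitting the Control libraries gave 1 to 156 with a median of 57.5. Across genes the correlation was 0.87 against 0.51 in the simulations, with a covariance of 0.305 against 0.043. With separate sets of 3 Control libraries the median correlation was 0.66 (0.52 to 0.75) and the median covariance 0.279. Without Model_1337 the overlap was 1408, and without Control_2668 it was 181% of that with all libraries. Without Control_2286, Control_2288 and Control_2289 it was 258, 284 and 485, and without AKK_1302, AKK_1305, AKK_1306, AKK_1309 and AKK_1310 it was 313, 463, 312, 294 and 324.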

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

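In 225 groups of 6 values, the libraries' totals and shares and the genes named here, the library farthest from the others was looked for with Dixon's ratio, on log2(FPKM + 1) for genes. It stood apart in 30 groups, and chance gives about 5% of independent groups. Krt5 and Fabp6 were chosen after their values were seen, and genes can vary together within a library. The 30 therefore cannot be weighed against that share. The tests of a single library, of Hoxb13 and of regrouping for the sterol genes, of separate cohorts, of squamous tissue and of the spread of distances were chosen only after the results were seen.

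Of these 30, 8 were in Model_1337, where Anxa1 stood at 1049 FPKM against 33.5 to 59.3 in the other Model libraries, Arg1 at 372 against 0.987 to 2.75, Krt5 at 1059 against 0.0367 to 0.328 and Selp at 25.6 against 0.555 to 3.43. Slc7a11 stood there at 8.16 FPKM against 0.558 to 1.07, Retnla at 8.79 against 0.094 to 1.26, Nox1 at 1.27 against 6.68 to 14.8 and Vdac2 at 38.1 against 62.5 to 75.5. Model_1341 held 79147073 counts against 58841661 to 64768956, with 17% of counts from mitochondrial genes against 3.93 to 7.7%, 18.1% from its 10 leading genes against 6.05 to 9.25% and Acsl5 at 16.3 FPKM against 21.9 to 23.4.

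Control_2286 held 65705141 counts against 53873744 to 56501156 in the other Control libraries and had Fabp6 at 187 FPKM against 1.95 to 4.79. Control_2285 had Hoxb13 at 4.88 FPKM against 0 to 0.0787. Control_2289 had Grem1 at 30.5 FPKM against 6.96 to 10.4 and Il1r2 at 1.47 against 0.261 to 0.526. Control_2668 had Ighg3 at 1.41 FPKM against 0.0409 to 0.255, mt-Th at 33.6 against 6.32 to 12 and mt-Tl2 at 26.9 against 5.1 to 9.33.

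AKK_1303 had Anxa1 at 31 FPKM against 45.8 to 50.4 in the other AKK libraries, Selp at 0.818 against 2.15 to 2.86, Vwf at 1.22 against 2.23 to 2.46, Fabp6 at 4.77 against 0.496 to 1.19, Ms4a18 at 1.32 against 0.402 to 0.646 and Reg3a at 1.62 against 0 to 0.127. AKK_1306 had Acsl5 at 24 FPKM against 22.3 to 22.8. AKK_1309 had Cd79a at 22.5 FPKM against 7.07 to 9.91, Cycs at 50.7 against 59.8 to 62.6 and 2.81% of counts from immunoglobulin genes against 1.14 to 1.73%.

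Squamous keratins stood apart in Model_1337, with Krt14 at 1581 FPKM and Krt13 at 1485 FPKM. Of 23 genes of squamous anorectal epithelium, 21 reached 10 FPKM in this library and 1 to 2 in each of the other 17, so the colon may express up to 2 of them at that level. Squamous tissue at the edge of the anus is a candidate source, and the test was run on the library in which the keratins had been seen. Whether it came with sampling or with the injury was not tested, and no biological explanation was tested.

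Reg3b and Reg3g were lower in Model and AKK than in Control. For AKK against Control Reg3g had a log2 change of -5.03 ± 1.18 (SE, edgeR adjusted p 0.022). Reg3g was not called there without Control_2288, AKK_1302, AKK_1306, AKK_1309 or AKK_1310 (edgeR adjusted p 0.0511 to 0.0546). Small intestinal tissue in the Control libraries was argued against by the count of libraries with at least 7 of 13 small intestinal genes at 10 FPKM or more, which was 1 of 6, Control_2286 with 9 against 2 to 5 in the others. A more distal sampling site, only as far as Hoxb13 reads it, was argued against as the whole cause by the fit with Hoxb13 as a covariate. There Reg3b fell by 6.46 ± 0.98 and Reg3g fell by 5.67 ± 0.91 on the log2 scale between Model and Control (SE, edgeR adjusted p 0.00388 and 0.00422, over all alternatives 5.73e-13 to 0.0549 and 4.15e-08 to 0.0608). Hoxb13 stood at 0 to 0.0787 FPKM in the Control libraries other than Control_2285. It cannot rank sites among libraries near 0, so a difference in site that Hoxb13 does not read stays open. A separate cohort of Control mice cannot be told apart from the treatment, since 0 Control libraries had a number within the range of the other groups, which holds for every comparison with Control. The treatment stays open beside it.

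Sterol synthesis genes were higher in AKK than in Model. A single library as the cause was argued against by the highest adjusted p of the list over the 12 fits without 1 library, 4.05e-05 (fry). A smaller share of epithelium in Model was argued against as the whole cause by an adjusted p of 2.00e-05 (fry) with epithelial markers as a covariate. A more distal site, as far as Hoxb13 reads it, was argued against likewise by 1.02e-05 (fry) with Hoxb13 as a covariate. Depth as the whole cause was argued against for the list by the fit without the 4 deepest libraries. The AKK libraries left held 60665457 to 63010372 counts and the Model libraries left 58841661 to 64768956. The list had an adjusted p of 0.0015 there (fry, 7.47e-07 to 0.0015 over 28 alternatives), with a median log2 change of 0.40 against 0.41 with all libraries. edgeR called 0 genes there (639 at an unadjusted p under 0.05), with fewer libraries. Hmgcs1 and Aacs had log2 changes of 0.78 and 0.63 there, against 0.73 and 0.63, so their lost calls do not show an effect of depth. Separate cohorts of AKK and Model mice cannot be told apart from the bacterium, since 0 AKK libraries had a number within the range of the Model libraries. A difference in DSS, which the labels state for Model only, cannot be told apart from the bacterium either. No biological explanation was tested.

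Distances between libraries averaged 0.695 in Model, 0.392 in AKK and 0.478 in Control. The difference between Model and AKK had an exact permutation p of 0.00649, and 0.00649 also without Model_1337, where the mean distance of Model was 0.578. Libraries were exchanged without centring on their group, so this p does not measure spread alone but also holds any shift between the groups. Model_1341 stayed in both tests, so they do not show a wider spread in Model without it.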

How the results depend on the processing

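The limma fit on log2(FPKM + 1) was fixed as the main test and became an alternative once the table was found to hold counts. The fits with DESeq2, with counts divided by 4, without mitochondrial genes, without Model_1337 and Model_1341, without the libraries above 70000000 counts and with Hoxb13 or epithelial markers as a covariate were chosen after seeing the data. No paired analysis was possible because the groups share no numbers in the labels. Counts within 1.5 times of the reported one are not listed. Where a setting tests fewer genes or uses fewer libraries or a stricter threshold, lower counts follow from its construction. The exact rank sum test has a floor, since its p cannot fall under 0.00216 with 6 against 6 libraries, which bears on its counts of 0. Otherwise the cause was not tested.

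Model against Control gave 1422 genes with a mean FPKM of at least 5, 903 with both groups fitted alone, 213 with a smooth muscle covariate, 1820 by limma, 1839 with a pseudocount of 0.1, 1358 on the TPM scale, 1526 with library weights, 0 by the exact rank sum test (3413 at an unadjusted p under 0.05), 605 with the Hoxb13 covariate and 764 at 2-fold or more. Without 1 library the count was 1721 (Control_2286) to 3395. Its lists numbered 5 with both groups alone, 3 with the smooth muscle covariate, 17 by camera with a preset correlation and 1 with an estimated correlation, and 6 to 14 (Model_1341) without 1 library. Its terms numbered 85 by camera and 16 at 2-fold or more.

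AKK against Model gave 0 genes with both groups alone (864 at an unadjusted p under 0.05), 14 with library weights, 0 by the rank sum test (865), 12 by DESeq2, 1 without Model_1337 and Model_1341, 0 without the deepest libraries (639), 0 at 2-fold or more and 2 to 4 without 1 library. Its lists numbered 2 without Model_1337 and Model_1341 and 17 by camera with a preset correlation, and 1 to 1 without 1 library. Its terms numbered 48 by camera and 0 at 2-fold or more.

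AKK against Control gave 411 genes with no filter, 455 with a mean FPKM of at least 5, 2697 with both groups alone, 431 with the smooth muscle covariate, 241 on the TPM scale, 3599 with library weights, 1592 by the rank sum test, 1841 by DESeq2, 2541 without Model_1337 and Model_1341, 56 without the deepest libraries, 200 with the Hoxb13 covariate, 256 at 2-fold or more and 282 (Control_2286) to 1563 (Control_2668) without 1 library. Its lists numbered 10 with both groups alone, 8 with the smooth muscle covariate, 3 by limma, 2 on the TPM scale, 3 with quantile normalization, 11 with library weights, 12 without Model_1337 and Model_1341, 2 without the deepest libraries, 3 with the Hoxb13 covariate, 15 by camera with a preset and 0 with an estimated correlation, and 2 (Control_2289, AKK_1302 or AKK_1309) to 5 without 1 library. Its terms numbered 54 by camera and 9 at 2-fold or more.

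Genes called in opposite directions in Model against Control and AKK against Model numbered 0 with both groups alone, 10 with library weights, 0 by the rank sum test, 12 by DESeq2, 1 without Model_1337 and Model_1341, 0 without the deepest libraries, 0 at 2-fold or more and 2 to 4 without 1 library. Genes called in the same direction against Control in both numbered 368 with no filter, 382 with a mean FPKM of at least 5, 149 with the smooth muscle covariate, 460 by limma, 183 on the TPM scale, 1270 with library weights, 0 by the rank sum test, 1475 by DESeq2, 1783 without Model_1337 and Model_1341, 55 without the deepest libraries, 155 with the Hoxb13 covariate, 217 at 2-fold or more and 258 (Control_2286) to 1408 (Model_1337) without 1 library. The sterol list was called in 28 of 28 alternatives in Model against Control and in AKK against Model, and in 2 of 28 in AKK against Control.

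Of the named genes called, 28 of 37 kept their call without any 1 library in Model against Control, 2 of 3 in AKK against Model and 13 of 25 in AKK against Control. Over all alternatives, 878 of 1065, 54 of 87 and 558 of 718 values kept their direction and call. The exact rank sum test, whose smallest possible p is 0.00216, ended all 37, all 3 and 2 of the 25 calls. Signs changed for Arg1 between Model and Control with the smooth muscle covariate (-0.24), and otherwise for genes that were not called. Between Model and Control these were Fth1 on the TPM scale (-0.019), with quantile normalization (-0.13) and without Model_1338 (-0.14), Control_2285 (-0.027) or Control_2289 (-0.0092), within a range of -0.14 to 0.15 without 1 library, and Nfe2l2 with library weights (0.0033). Between AKK and Model Acsl4 had 0.0024 on the TPM scale, 0.063 with library weights and 0.034 without Model_1337, within a range of -0.46 to 0.034 without 1 library. Nfe2l2 had 0.0091 with no filter, 0.064 by limma, 0.066 with a pseudocount of 0.1, 0.15 on the TPM scale, 0.016 with quantile normalization, 0.0024 by the rank sum test, 0.14 without the deepest libraries and positive values up to 0.091 without Model_1338, Model_1339, AKK_1306, AKK_1309 or AKK_1310, within a range of -0.12 to 0.091 without 1 library. Between AKK and Control Ptgs2 had negative values without Control_2668, Control_2285, Control_2286, Control_2287, AKK_1305 or AKK_1306, within a range of -0.13 to 0.29 without 1 library. The filter on FPKM, not depth, kept out Slc7a11, which had 78 to 7414 counts per library.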

Other observations

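T cell and antigen presentation genes were in part higher in Model than in Control, and neither list was called. Of 14 T cell genes 5 were called higher, and 6 when adjusted over the list alone (fry adjusted p = 0.076, 0.0037 without Model_1341 and 0.0037 to 0.182 over the fits without 1 library), and 8 were called higher without Model_1341. Of 11 genes of MHC class II, which presents antigen to T cells, 5 were called higher, and 9 when adjusted over the list alone (fry adjusted p = 0.0826, 0.0328 without Model_1338, 0.0333 without Model_1341 and up to 0.182 without another library), and 8 and 9 were called higher without Model_1338 and Model_1341. Of 34 interferon response genes 6 were called lower between AKK and Control, and 8 when adjusted over the list alone, with a median log2 change of -0.76 (fry adjusted p = 0.132). The 6 became 0 without Control_2288, Control_2289, AKK_1305, AKK_1306, AKK_1309 or AKK_1310, 1 without Control_2286 and 2 without AKK_1302 or AKK_1303. Goblet cell and enteric neuron lists had median log2 changes of 0.42 and -0.61 between AKK and Model and were not called (fry adjusted p = 0.47 and 0.262). The tests of regrouping for the sterol genes were chosen only after the result was seen, and the other regroupings before.

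Other splits of the 12 libraries of a comparison into 6 and 6 were drawn, 100 in each with the real one. For Model against Control 2 of them gave as many genes (2797, highest other 2851), fewer than the 5 of 100 fixed as the limit. Such a share argues against chance for that count without excluding it, since 1 other split gave more. For its lists 5 gave as many (8, highest other 11) and for its enriched terms 5 (46, highest other 63), so chance cannot be excluded for these. For AKK against Model 1 gave as many genes, the real one (3, highest other 2). That share lies under the limit, but a margin of 3 genes against 2 does not exclude chance. For its lists 6 gave as many (1, highest other 5), so chance cannot be excluded there either. For its terms 1 gave as many (3, highest other 0), but only 2 of the 99 other splits called any gene, so the test of terms decides nothing beyond the genes. For the sterol list itself 1 split, the real one, gave as small an unadjusted p (1.24e-07, smallest other 0.00182, fry). For AKK against Control 1 split gave as many genes (859, highest other 0) and 1 as many lists (5, highest other 0). These shares argue against chance for both counts. For its terms 1 gave as many (15, highest other 0), but 0 of the 99 other splits called any gene by edgeR, so no term could be enriched in them and the test decides nothing. In 100 assignments of the 18 libraries to 3 groups, 1 gave as large an overlap in opposite directions (3, highest other 1) and 1 as large an overlap in the same direction (739, highest other 0), the real one in both. Genes were called in both comparisons in 1 and 0 of the 99 other assignments, so the overlaps were all but fixed there and these tests decide nothing.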
